A study of Mus musculus with 4 samples.

How the data were processed

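RNA of mouse oligodendrocytes was profiled by sequencing in 4 libraries, 2 per genotype. Per the labels, the cells came from the cortex of C57BL/6 pups at postnatal day 5. They were purified by immunopanning, a method in which cells are captured on dishes coated with antibodies, here against the lipids GalC and then O4. They grew for 6 days, were switched to differentiation medium with 40 ng/mL of the thyroid hormone T3, and were harvested 24 h later. Control cells carried floxed alleles of Zdhhc5 alone. Conditional knockout cells, called cKO below, also carried Cre recombinase in the Olig1 locus, which deletes the floxed gene in the oligodendrocyte lineage. The labels do not say whether the 2 libraries of a genotype came from separate cultures or animals. P-values therefore rest on the spread between these libraries, pooled in part over the listed genes, and that spread may be technical.

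The authors deposited 1 table with a normalised signal per gene and library (read counts divided by 1 size factor per library), the mean of each genotype, a log2 fold change, a p-value, an adjusted p-value and the gene's length, per the file headers. The size factors were read from the values themselves. The submitters' processing notes name DESeq2, with no version, and the genome builds mm10 and GRCm38, which are names of the same mouse assembly. The aligner, the counting tool, the strand setting and the annotation release were not given in the sources used here. No column of another sample was present (0 columns).

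The values of each library were whole multiples of 1 step, so whole reads could be recovered. Within 0.01 read, 100% of the 6940 values of each library came out whole. A read was worth 1.0 in control 1, 1.0181 in control 2, 0.8165 in cKO 1 and 1.1866 in cKO 2. The listed genes held 17077509, 16773675, 20068016 and 13672254 reads in these libraries. These sums cover the listed genes only and are not the depth of the whole libraries.

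The table as analysed here lists only genes that the authors called. All 6940 have an adjusted p-value in the authors' deposited table under 0.05, the largest being 0.0499. The adjusted p-value times the gene's rank over its p-value gave 17347 from the top to the bottom of the table, so 17347 genes lay behind the adjustment and 40.0% of them were listed. For this reason the Benjamini-Hochberg adjustment over genes took 17347 as the number of genes tested, except in an alternative that adjusted over the listed genes only. Comparisons of a gene list with other genes are comparisons with other called genes. Zdhhc5, the deleted gene, and Stat3, which the rule for named genes also included, were not analysed here. The genotype labels were therefore not checked by the level of the deleted gene. A read count over a whole gene would in any case not read a deleted exon on its own.

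Genotypes were compared with limma on log2(value + 1) with a trend of variance with mean, genotype as the only term and 2 residual degrees of freedom. The variance of each gene was drawn toward that of listed genes of a like level. These genes had been selected for their difference, so the pooled variance may be too small and the p-values too low. Genes needed a value of at least 1 in 2 or more libraries, and all 6940 passed. Log2 fold changes, and the counts of genes past a fold, are on the log2(value + 1) scale, which understates the change of low genes. A change of a named gene given as a fold is the ratio of the mean normalised reads. The planned test for counts, the quasi-likelihood test of edgeR, was moved to the alternatives because the deposited values were normalised. An adjusted p under 0.05 was taken as a call. Because the genes had been selected for their difference, calls of the same libraries here are not independent evidence. This was tested on simulated data. With 200 of 6940 genes changed, limma recovered 70% of genes changed 1.25-fold, 88% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold, with 2 false calls. When 17347 simulated genes were first selected with DESeq2, 24 of the 5795 selected genes were unchanged, and limma called all 24 again. The levels and spreads of all simulated genes were drawn from the listed genes. Unlisted genes were therefore not represented, and this count does not estimate the false calls in the real table.

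The gene lists and the rule for named genes, the test, the threshold, the filter and most alternatives were fixed before the data were examined. There were 16 lists of pathways and of stages of the oligodendrocyte lineage, and 5 lists of markers of other cell types. Some genes stand in a pair of lists, among them Gfap (STAT3 targets and astrocytes), Fos and Junb (STAT3 targets and immediate early genes), and Ugt8a and Fa2h (myelin and fatty acid synthesis). Many astrocyte markers, such as Clu, Aldoc and Slc1a3, are also expressed by oligodendrocyte precursors. The named genes were Olig1, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 normalised reads, non-overlapping genotypes and a regular symbol, and up to 4 members of each list with the lowest p, 100 genes in all, a few of which are not reported here. Where a named gene that is reported kept less than 67% of its log2 fold change with the trend with GC content, or with GC content and length, removed, such a value is given beside it, by a bound chosen after the data were seen. Other members of a list serve as examples, chosen after their values were seen.

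Lists were tested with camera of limma, two-sided, with its preset correlation of 0.01, and adjusted over the 21 lists by the Benjamini-Hochberg method. Alternatives were camera with an estimated correlation and fry of limma. After the data were seen, each list was also compared with 10000 random lists of other listed genes with the same GC content, for which the smallest p is 0.0001. A Fisher's exact test asked whether members rose or fell more often than other listed genes, and a hypergeometric test asked whether more members were listed than chance gives. That last test took every member as tested by the authors. For every list, all listed members also passed when adjusted over the list alone. That adds no support, because every listed gene had already been called with adjustment over 17347 genes. The GC content was that of the longest transcript of the gene in GENCODE release M21 on GRCm38, which held 6934 of the 6940 gene identifiers (99.9%). The coordinates of 6668 genes (96.1%) were the same in both. For 16 genes whose symbols had been turned into dates, symbols were restored from the identifiers.

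Other settings fixed in advance were the library number as a block, each library left out in turn, TMM scaling computed on the values, no filter, the Wald test of DESeq2 and limma-voom on recovered reads, the authors' deposited p-values, pseudocounts of 0.1 and 10, an adjusted p under 0.01 and a fold of at least 1.5. Added after the data were seen were the quasi-likelihood test of edgeR on recovered reads with TMM or relative log expression factors, adjustment over the listed genes only, and removal of the trend of each library with GC content, or with GC content and then gene length, by loess with a span of 0.5. Because only called genes were present, such a removal takes out part of any change that itself follows GC content. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

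Replicates were compared before they were averaged. Over genes with at least 20 reads in a pair, chi-square per degree of freedom was 2.31 between the controls (6908 genes) and 3.24 between the cKO libraries (6861 genes). Both lay above the value of 1 that read sampling alone gives. That shows spread beyond read sampling, not that the libraries came from separate cultures or animals. Each library was counted as a separate sample. The median absolute log2 difference was 0.057 between the controls and 0.07 between the cKO libraries. Near-identical gene copies, such as H2-K1 with H2-D1 and Tmem254c with its neighbours, and antisense genes such as Bcas1os2 are uncertain, because counting that splits or shares their reads was not described.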

Results

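Messenger RNA was measured in oligodendrocytes, the myelin-forming cells of the brain, from mouse cortex after 24 h of differentiation in culture. There were 2 control libraries and 2 libraries of conditional knockout (cKO) cells, in which Cre expressed from the Olig1 locus deletes Zdhhc5. Zdhhc5 encodes an enzyme that attaches the fatty acid palmitate to proteins. The listed genes held 17077509 and 16773675 recovered reads in the controls and 20068016 and 13672254 in the cKO libraries. Values below are normalised read counts, given as mean ± SD with n = 2 libraries per genotype.

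The study's design asks which mRNAs differ between oligodendrocytes with and without Zdhhc5. Only the cKO cells carried Cre in the Olig1 locus, so effects of Cre or of the changed locus cannot be told apart from those of Zdhhc5. Myelin mRNAs were far lower in the cKO cells. Mbp, which encodes myelin basic protein, fell from 124326 ± 6.3 to 16415 ± 443 normalised reads, and Cldn11, the tight junction protein of myelin, fell from 31673 ± 63.0 to 6807 ± 269. Sox10 and Myrf, transcription factors that drive myelin genes, fell 2.69-fold and 3.44-fold. Markers of pericytes and fibroblasts rose, with Col3a1 going from 1762 ± 23.3 to 5600 ± 237, and the astrocyte filament gene Gfap rose from 351796 ± 446 to 555415 ± 2590.

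All 6940 listed genes passed in limma, 3244 higher and 3696 lower in the cKO cells, which is the same count in each direction as in the authors' deposited table. Changes of at least 1.5-fold numbered 1209 upward and 1914 downward. Among the 1205 genes that changed at least 2-fold, 811 fell and 394 rose, so 67.3% of the larger changes were falls. Both cKO values lay above both control values in 3243 genes and below them in 3696, where chance gives 33.3% of genes in all. The exception, Scand1, was singled out after its values were seen. Only genes already called by the authors were listed, so these counts are not independent of that call. With the trend with GC content removed, 2822 genes were higher and 2151 lower (56.7% higher, against 46.7% before), and relative log expression factors raised all fold changes by a median of 0.191 on the log2 scale, with 3250 genes higher and 2927 lower (52.6% higher), so that directions stated here are relative to the authors' scaling.

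Olig1, the gene whose locus carries Cre and which encodes a lineage transcription factor, fell from 11990 ± 64.6 to 6845 ± 574 normalised reads, 1.75-fold lower (log2 fold change -0.81, SE 0.04, limma adjusted p 2.48e-14). The gene, ENSMUSG00000046160, lies on chromosome 16 from 91269772 to 91271933 of GRCm38. The knocked-out gene itself was not analysed here.

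Genes of myelin and mature oligodendrocytes fell as a group. Of 25 list members 19 were listed, and 16 of these fell and 3 rose, with a median log2 fold change of -2.23 (camera adjusted p 8.59e-05, and adjusted p = 0.352 with an estimated correlation). Mbp (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637) was 7.57-fold lower, with a log2 fold change of -2.92 (SE 0.03, limma adjusted p 3.29e-28). Mag, an adhesion protein of the inner myelin membrane, fell from 12059 ± 8.8 to 2094 ± 44.3, 5.76-fold lower, and Cldn11 was 4.65-fold lower. Mobp fell further, from 1350 ± 18.5 to 78.3 ± 0.0, 17.2-fold lower. Members that rose were Apod, Car2 and Gsn, with log2 fold changes of 2.35, 0.63 and 0.19, that of Gsn turning to -0.09 with the GC trend removed. Apod encodes a lipid carrier also made by fibroblasts and pericytes, Car2 a carbonic anhydrase and Gsn an actin-severing protein. Random lists with the same GC content had medians from -0.38 to 0.46 (95% range, adjusted p 0.0007), and the median was -1.88 with the GC trend removed and -2.03 with GC content and length removed.

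Genes of newly formed oligodendrocytes fell in every listed case. Of 24 members 23 were listed and all 23 fell, with a median log2 fold change of -1.36 (camera adjusted p 9.89e-10, and adjusted p = 0.352 with an estimated correlation). Enpp6, a phosphodiesterase that marks cells entering differentiation, fell from 17018 ± 417 to 3098 ± 3.1, 5.49-fold lower (log2 fold change -2.46, SE 0.04, limma adjusted p 7.37e-25). Nfasc, which encodes the adhesion molecule neurofascin, fell 4.08-fold, Myrf 3.44-fold and Bcas1 2.97-fold. The smallest fall was that of Samd4b, with a log2 fold change of -0.47. Members were listed more often than chance gives (hypergeometric test, adjusted p 2.15e-07), which held for 11 of the 21 lists, evenly split precursor genes among them (adjusted p 0.00225). Random lists with the same GC content had medians from -0.35 to 0.43 (adjusted p 0.0007), and the median was -1.51 with the GC trend removed and -1.46 with GC content and length removed.

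Transcription factors of the oligodendrocyte lineage fell too, 17 of 18 members being listed and all 17 lower, with a median log2 fold change of -0.81 (camera adjusted p 1.29e-05, and adjusted p = 0.352 with an estimated correlation). Sox10 fell from 16985 ± 11.2 to 6326 ± 236 (log2 fold change -1.43, SE 0.03, limma adjusted p 8.05e-21), Zfp488 fell 3.92-fold and Zeb2 fell 2.08-fold, the log2 fold change of Zeb2 being -1.06, -0.38 with the GC trend removed and -0.10 with the trends with GC content and length both removed. Olig2 and Nkx2-2, which specify the lineage, had log2 fold changes of -0.52 and -0.71. Random lists with the same GC content had medians from -0.44 to 0.45 (adjusted p 0.0007), and the median was -0.96 with the GC trend removed and -0.94 with GC content and length removed.

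Precursor genes split evenly. Of 24 members 18 were listed, 9 higher and 9 lower, with a median log2 fold change of -0.08 (camera adjusted p 0.986), -0.01 with the GC trend removed and 0.08 with GC content and length removed. Pdgfra, the growth factor receptor that defines oligodendrocyte precursors, fell from 3746 ± 228 to 2063 ± 19.2, and Lhfpl3 fell 3.57-fold (log2 fold change -1.84, and -1.22 with the GC trend removed). Cspg5, a proteoglycan, rose 1.62-fold, and Serpine2 rose with a log2 fold change of 0.42. Genes of proliferation were also mixed, with 11 of 32 members listed, 6 higher and 5 lower, a median log2 fold change of 0.34 and a mean of -0.02 (camera adjusted p 0.651). The median was 0.22 with the GC trend removed and 0.20 with GC content and length removed. Mki67, a marker of cycling cells, fell 1.54-fold (log2 fold change -0.62, and -0.22 with GC content and length removed) and Kif11, a motor of the mitotic spindle, fell 1.52-fold, while Rrm2, which supplies nucleotides for DNA synthesis, rose 1.42-fold. With the GC trend removed, Kif11 no longer passed (log2 fold change -0.03).

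**Figure D1:**
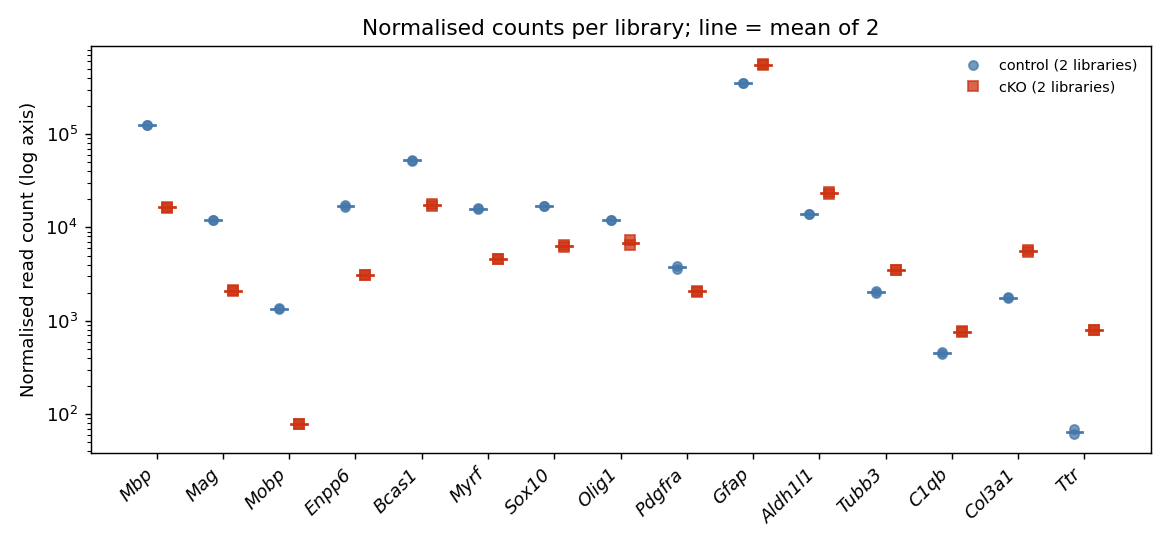
Normalised read count (log axis) of selected genes in each library, with control circles, cKO squares and a short line at the mean of 2 libraries. The myelin genes Mbp and Mag lie lower in both cKO libraries, while Gfap, Col3a1 and Ttr lie higher.

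Lipid synthesis genes showed a few large falls within mixed lists. In cholesterol synthesis 14 of 24 members were listed, 3 higher and 11 lower, with a median log2 fold change of -0.28 (camera adjusted p 0.0949). The median was -0.04, with 6 members above and 8 below 0, with the GC trend removed and -0.09 with GC content and length removed. Hsd17b7 fell from 5300 ± 124 to 1669 ± 80.3, whereas Lss, which forms lanosterol, fell 1.33-fold (log2 fold change -0.41, and -0.16 with GC content and length removed) and Hmgcs1, an early enzyme of the pathway, 1.28-fold. The direction of Hmgcs1 turned when the GC trend was removed (log2 fold change 0.16). In fatty acid and sphingolipid synthesis 19 of 22 members were listed, 6 higher and 13 lower, with a median log2 fold change of -0.28 (camera adjusted p 0.227), which was -0.12 with the GC trend removed and -0.11 with GC content and length removed. Ugt8a, which makes the myelin lipid galactocerebroside, fell from 14117 ± 69.0 to 2930 ± 9.7, 4.82-fold lower, with a log2 fold change of -2.27 that became -1.42 with the GC trend removed. Elovl7, a fatty acid elongase, fell 3.65-fold and Fa2h, which hydroxylates myelin fatty acids, fell 2.87-fold. Thrsp, a regulator of lipid synthesis, rose 2.19-fold. The antigens used for panning, GalC and O4, are products of this pathway.

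Markers of other cell types rose in the same libraries in which the oligodendrocyte lists fell. Among pericyte and fibroblast markers 10 of 12 were listed and all 10 rose, with a median log2 fold change of 1.58 (camera adjusted p 7.99e-05, and adjusted p = 0.352 with an estimated correlation). The collagen genes Col3a1, Col1a2 and Col1a1 rose 3.18-fold, 3.22-fold and 3.41-fold, and Dcn, which encodes the matrix proteoglycan decorin, rose 3.42-fold (log2 fold change 1.77, and 2.66 with the GC trend removed). GC-matched lists had medians from -0.45 to 0.56 (adjusted p 0.00105), and the median was 1.44 with the GC trend removed and 1.40 with GC content and length removed. Endothelial markers were mostly unlisted, 3 of 10, and moved apart, as Cdh5 rose from 13.1 ± 4.4 to 87.3 ± 9.3 and Emcn rose 3.79-fold (log2 fold change 1.86, and 2.53 with the GC trend removed) while Kdr fell 1.91-fold. Their median log2 fold change of 1.86 was not called by camera (adjusted p 0.553) and lay outside the range of GC-matched lists, -1.03 to 0.77 (adjusted p 0.00315), being 2.53 with the GC trend removed and 2.51 with GC content and length removed.

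Astrocyte markers rose by less. Of 12 members 10 were listed, 9 higher and 1 lower, with a median log2 fold change of 0.63 (camera adjusted p 5.84e-04, and adjusted p = 0.355 with an estimated correlation). Gfap rose 1.58-fold (log2 fold change 0.66, SE 0.03, limma adjusted p 7.22e-17, and 0.37 with GC content and length removed) and had the highest count of any listed gene in all 4 libraries, 2.06% of the listed counts in each control and 3.4% and 3.41% in cKO 1 and cKO 2. In comparison, Mbp took 0.73% in each control and 0.1% in each cKO library. Clu rose 1.72-fold (log2 fold change 0.78, and 0.46 with GC content and length removed), Aldh1l1, an enzyme of folate metabolism used as a general astrocyte marker, rose 1.68-fold, and Aldoc rose 1.55-fold. Aqp4, a water channel, was lower, with a log2 fold change of -0.16, which turned to 0.47 with the GC trend removed. Beside GC-matched lists the astrocyte median was not called (range -0.55 to 0.51, adjusted p 0.094), and it was 0.54 with the GC trend removed and 0.48 with GC content and length removed.

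Neuron markers were listed for 9 of 12 members, 8 higher and 1 lower, with a median log2 fold change of 0.67 (camera adjusted p 0.0314, and adjusted p = 0.352 with an estimated correlation). Tubb3, a neuronal tubulin, rose from 2021 ± 69.9 to 3500 ± 36.8 (log2 fold change 0.79, and 0.35 with GC content and length removed), and Gad1, which makes the transmitter GABA, rose 1.65-fold. Dcx, a microtubule protein of young neurons, fell 1.32-fold, and its direction turned with the GC trend removed (log2 fold change 0.28). The list's call was lost without cKO 1 (camera adjusted p 0.0648) and without cKO 2 (0.0774), and its median lay above that of GC-matched lists (-0.81 to 0.37, adjusted p 0.00315), being 0.91 with the GC trend removed and 1.00 with GC content and length removed. Microglia markers were listed for 7 of 12 members, all 7 higher, with a median log2 fold change of 0.70 (camera adjusted p 0.0163, and adjusted p = 0.355 with an estimated correlation). C1qb, a complement component, rose 1.70-fold from a low level of 449.9 ± 20.0 (log2 fold change 0.77, and 0.31 with GC content and length removed), and Trem2 rose 1.68-fold. The microglia call was lost without cKO 1 (camera adjusted p 0.0616), without cKO 2 (0.113), with the GC trend removed (0.0692, median 0.53) and with GC content and length removed (0.189, median 0.35).

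**Figure D2:**
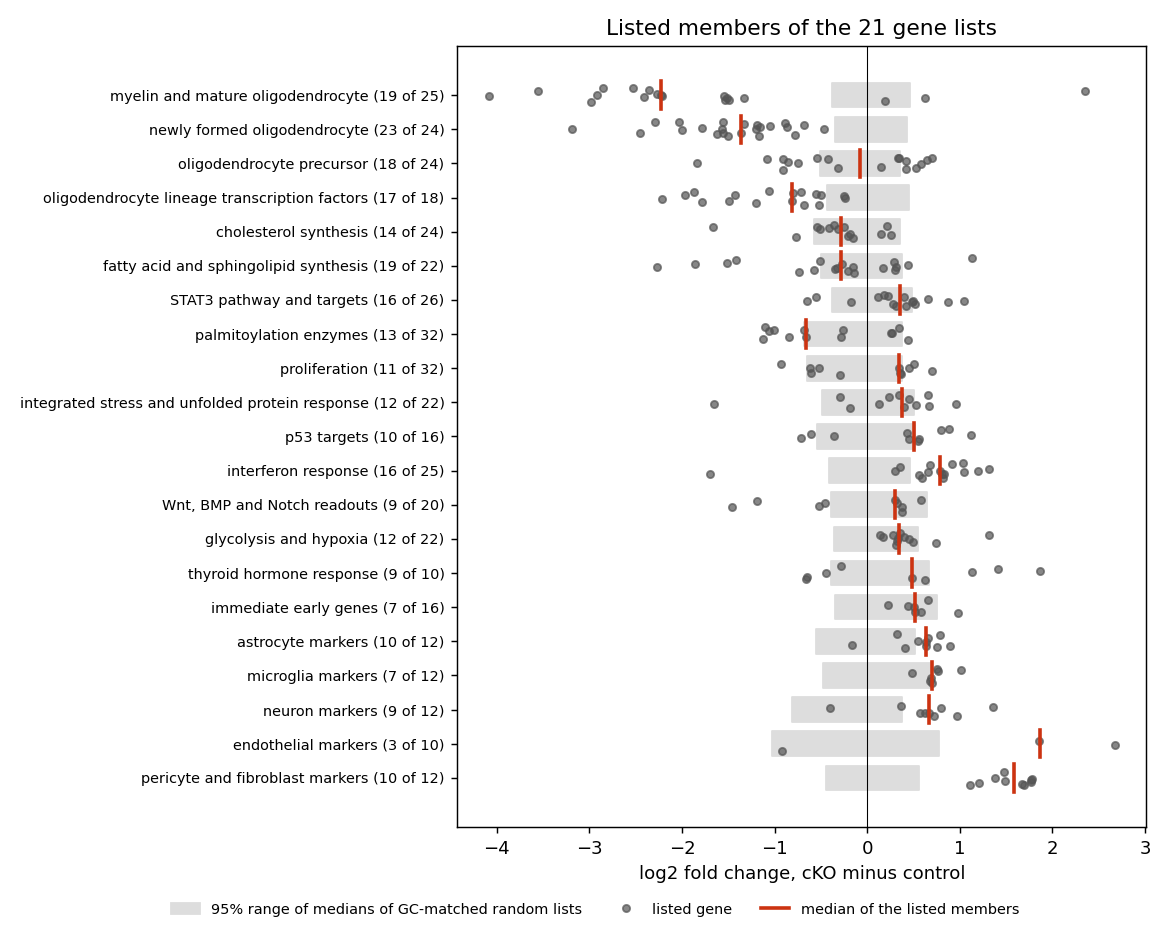
Log2 fold change (cKO minus control) of each listed member of the 21 gene lists, with the listed of all members beside each name, a red line at the list's median and a grey bar for the 95% range of medians of GC-matched random lists. The medians of myelin, newly formed oligodendrocyte and lineage transcription factor lists lie at -2.23, -1.36 and -0.81, to the left of their bars.

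Interferon response genes rose, with 16 of 25 members listed, 15 higher and 1 lower, and a median log2 fold change of 0.79 (camera adjusted p 0.00298, and adjusted p = 0.352 with an estimated correlation). Tap1, a peptide transporter, was 1.75-fold higher, Gbp2, an interferon-induced GTPase, 1.51-fold higher and H2-K1, whose reads can be shared with related class I genes, 1.47-fold higher (log2 fold change 0.55, and 0.23 with GC content and length removed). Mx2, which is annotated as a polymorphic pseudogene, fell from 187.8 ± 13.8 to 57.1 ± 3.6. Members rose more often than other listed genes did (Fisher's exact test, adjusted p 7.33e-04), but the median was not called beside GC-matched lists (-0.41 to 0.46, adjusted p 0.094), being 0.84 with the GC trend removed and 0.73 with GC content and length removed. Members of the STAT3 pathway and its targets were listed for 16 of 26, 13 higher and 3 lower, with a median log2 fold change of 0.35 (camera adjusted p 0.0163, and adjusted p = 0.441 with an estimated correlation). Cebpd, a transcription factor of the acute phase response, rose 1.83-fold and Osmr, a cytokine receptor, rose 1.40-fold. Gfap is a member of this list as well. Hif1a fell 1.57-fold, and its value was near 0 with the GC trend removed (log2 fold change -0.02). The STAT3 call was lost with the GC trend removed (camera adjusted p 0.0512, median 0.24, and 0.09 with length removed as well), and its median lay within that of GC-matched lists (-0.38 to 0.48, adjusted p 0.68). Stat3 itself was not analysed here.

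Glycolysis and hypoxia genes rose by small amounts, 12 of 22 members being listed and all 12 higher, with a median log2 fold change of 0.34 (camera adjusted p 6.28e-04, and adjusted p = 0.352 with an estimated correlation). Pfkp, a phosphofructokinase, rose 1.68-fold, Hk1, a hexokinase, 1.37-fold and Eno1, an enolase, 1.32-fold. With the GC trend removed the log2 fold change went from 0.45 to 0.19 for Hk1 and from 0.40 to 0.12 for Eno1. Pkm rose 1.28-fold and no longer passed with the GC trend removed (log2 fold change 0.07). This median lay within that of GC-matched lists (-0.36 to 0.55, adjusted p 0.794), and the call was lost when the trends with GC content and length were both removed (camera adjusted p 0.114, median 0.18, and 0.16 with GC content alone removed). Immediate early genes, the rapid transcription factors of stimulated cells and their partners, were listed for 7 of 16 members, all 7 higher, with a median log2 fold change of 0.51 (camera adjusted p 0.0112, and adjusted p = 0.352 with an estimated correlation). Btg2 rose 1.97-fold, Jund 1.58-fold and Junb 1.42-fold, although Jund and Junb no longer passed with the trends with GC content and length both removed (log2 fold changes 0.07 and 0.02). That call was lost without cKO 1 (camera adjusted p 0.0521) and with the GC trend removed (0.104, median 0.23, and 0.11 with length removed as well), and GC-matched lists had medians from -0.35 to 0.75 (adjusted p 0.527).

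Targets of p53 were listed for 10 of 16 members, 7 higher and 3 lower, with a median log2 fold change of 0.50 (camera adjusted p 0.0787), which was 0.39 with the GC trend removed and 0.32 with GC content and length removed. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 2398 ± 47.3 to 5219 ± 99.5, 2.18-fold higher, Fas rose 1.84-fold and Phlda3 1.74-fold, the log2 fold change of Phlda3 being 0.80 and, with GC content and length removed, 0.27. Trp53inp1 fell 1.65-fold and no longer passed with the GC trend removed (log2 fold change 0.07). Genes of the integrated stress and unfolded protein response were listed for 12 of 22 members, 9 higher and 3 lower, with a median log2 fold change of 0.37 (camera adjusted p 0.133), which was 0.32 with the GC trend removed and 0.25 with GC content and length removed. Phgdh, the first enzyme of serine synthesis, rose 1.59-fold (log2 fold change 0.67, and 0.27 with GC content and length removed) and Pdia4, a chaperone of the endoplasmic reticulum, 1.37-fold, while Vldlr, a lipoprotein receptor, fell 3.14-fold (log2 fold change -1.65, and -1.06 with GC content and length removed).

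Thyroid hormone response genes, relevant because T3 was in the medium, were listed for 9 of 10 members, 5 higher and 4 lower, with a median log2 fold change of 0.48 (camera adjusted p 0.553), which was 0.28 with the GC trend removed and 0.18 with GC content and length removed. Klf9 and Hr, direct targets of the hormone receptor, fell 1.57-fold and 1.58-fold, while Thrsp and Dbp rose 2.19-fold and 1.55-fold, the log2 fold change of Dbp going from 0.63 to 0.18 with GC content and length removed. Readouts of Wnt, BMP and Notch signalling were listed for 9 of 20 members, 5 higher and 4 lower, with a median log2 fold change of 0.30 and a mean of -0.19 (camera adjusted p 0.553). Their median was 0.07 with the GC trend removed and turned to -0.10, with 3 members above and 6 below 0, with GC content and length removed. Smad7, an inhibitor of BMP and TGF-beta signalling, fell 2.75-fold and the ligand gene Bmp4 2.28-fold, while Apcdd1 and Notch1 rose 1.49-fold and 1.30-fold, the log2 fold change of Notch1 going from 0.38 to 0.10 with the GC trend removed.

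Palmitoylation enzymes, the family to which Zdhhc5 belongs together with partners and thioesterases, were listed for 13 of 32 members, 4 higher and 9 lower, with a median log2 fold change of -0.66 (camera adjusted p 0.16). Zdhhc2 fell from 1330 ± 11.9 to 611.0 ± 48.8, 2.18-fold lower (log2 fold change -1.12, and -0.53 with GC content and length removed), and Zdhhc21 fell 2.00-fold, though Zdhhc21 no longer passed with the trends with GC content and length both removed (log2 fold change -0.04). Abhd17b, which removes palmitate, fell 2.08-fold (log2 fold change -1.06, and -0.20 with the GC trend removed), and Golga7, a partner of Zdhhc9 and of Zdhhc5, fell 1.61-fold (log2 fold change -0.69, and -0.24 with GC content and length removed). GC-matched lists had medians from -0.68 to 0.38 (adjusted p 0.474). The median was -0.23 with GC content and length removed. With the GC trend removed it was -0.20 and the list was called by camera (adjusted p 0.0235), but not with an estimated correlation (adjusted p = 0.295) or with the library number as a block (adjusted p 0.054).

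The largest falls were led by oligodendrocyte genes. Tppp, which encodes a microtubule protein of myelinating cells, fell from 8659 ± 76.3 to 459.7 ± 64.7 normalised reads, 18.8-fold lower (log2 fold change -4.24, SE 0.06, limma adjusted p 1.31e-24). The potassium channel gene Kcnj12 fell 8.79-fold. Tmem125, Sytl5, Ptprb, Thsd4 and Btbd16 fell between 8.27-fold and 15.5-fold, the lowest being Sytl5 at 8.7 ± 3.9 normalised reads in the cKO cells. Bcas1os2, 8.37-fold lower, is antisense to Bcas1, and its reads could not be told from those of Bcas1 without the strand setting. The largest rise was that of Ttr, the carrier of thyroid hormone and retinol, from 65 ± 5.6 to 789.5 ± 2.3 normalised reads, 12.1-fold higher (log2 fold change 3.58, SE 0.12, limma adjusted p 5.79e-18). Apod rose 5.12-fold. Also among the 10 largest rises were Cyp26b1 (4.32-fold), which degrades retinoic acid, Aldh1a2 (3.84-fold), which makes it, Slc6a13 (4.48-fold), a GABA transporter of the meninges, the collagen gene Col15a1 (5.51-fold), the endothelial cadherin gene Cdh5 (6.64-fold), the vasoactive peptide gene Adm (4.65-fold) and Itih2 (4.19-fold). Tmem254c was counted at 138.8 ± 111 in the cKO libraries, which differed widely, and has near-identical copies. Its log2 fold change was 1.95, 2.86 without cKO 1 and 1.03 without cKO 2.

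Fold changes followed the GC content of transcripts. Across 6934 genes, which are not independent replicates, the log2 fold change correlated with GC content at a Spearman rho of 0.51 and a Pearson r of 0.45, and with log length at a rho of -0.34. Among genes with the lowest GC content (31.0 to 40.6%) the median log2 fold change was -0.76 and 5.9% of genes rose. Among those with the highest (58.1 to 72.8%) it was 0.41 and 80.5% rose. The difference between cKO 1 and cKO 2 correlated with GC content at a rho of 0.17, and that between the controls at -0.02. All these trends rest on genes selected for a difference between genotypes in these same libraries. Trends within and between genotypes therefore cannot be compared on equal terms.

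**Figure D3:**
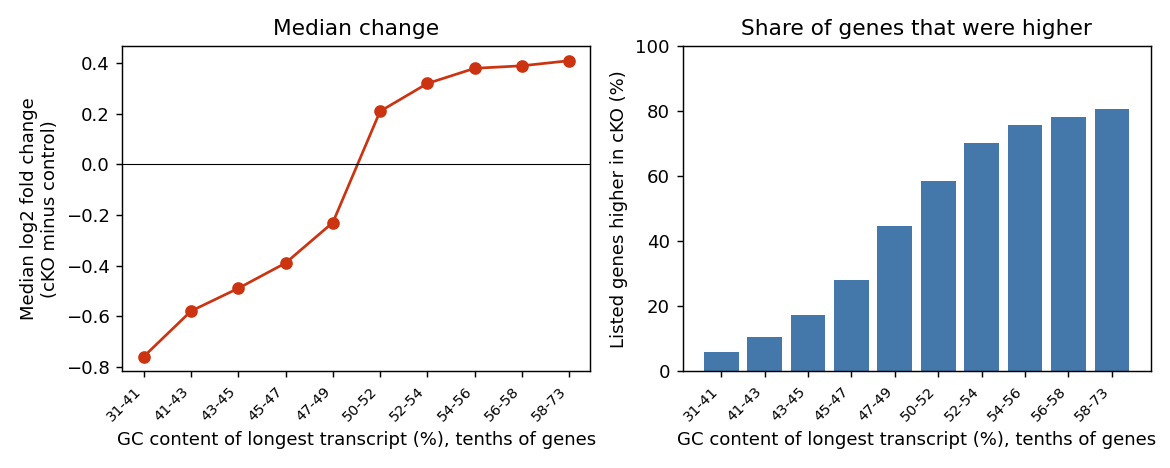
Median log2 fold change (left) and percentage of listed genes higher in cKO (right) in 10 bins of GC content, each with about a like number of genes. The median rises from -0.76 to 0.41 and the percentage from 5.9 to 80.5 between the lowest and the highest bin.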

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

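The GC, length, edgeR, listed-only and GC-matched settings were chosen after the data were seen, and the others before. The number of changed genes, 6940, ranged from 4854 to 6940 over all settings that kept the fold open. Without each library in turn, 6725 to 6912 genes were called, 3137 to 3228 higher and 3588 to 3684 lower, the lone library of a genotype being assumed to vary like the other genotype. The count was 6938 with the library number as a block. The deviations of control 1 and cKO 1 correlated at -0.017 across genes, which gave no sign of pairing but cannot exclude it. The block ended the calls of the microglia and neuron lists (camera adjusted p 0.0547 for both). DESeq2 called 6926, limma-voom 6850, edgeR 6841 and 6177 with relative log expression factors. Lower genes numbered 2151 with the GC trend removed, 2118 with GC and length removed and 2176 with the block and GC removed. A fold of at least 1.5 left 3123 genes, 1209 higher and 1914 lower, by its own construction. Of the 21 lists, 11 were called by camera, 0 with an estimated correlation, 0 with that and the GC trend removed, and 6 beside GC-matched lists. By fry 19 were called, a test of whether members move one way on balance without comparing them with other genes. Every member given to fry had already been called different between genotypes in these libraries, so its calls add no independent support. Without each library in turn 8 to 11 lists were called. With an estimated correlation, the unadjusted camera p of the newly formed list went from 4.71e-11 to 0.0184. Yet its estimate, -0.005, lay below the preset 0.01. For pericyte and fibroblast markers, with an estimate of 0.002, that p went from 1.14e-05 to 0.0452. A correlation above the preset therefore cannot account for the lost calls of these lists. Other lists had higher estimates, such as 0.316 for astrocyte markers. What else lay behind the differences between settings was not tested further.

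Named genes kept direction and call in 1776 of their values under alternatives, lost the call in 14 and changed sign, called or not, in 10. All 24 of these were under removal of the GC trend, alone, with length or with the block. In that order of settings, log2 fold changes became 0.16, 0.13 and 0.16 for Hmgcs1 and 0.073, 0.13 and 0.073 for Trp53inp1. For Dcx they became 0.28, 0.45 and 0.28, and with length Hif1a became 0.014. The values of 0.073 and 0.014 did not pass. Among all listed genes, 1175 changed sign with the GC trend removed, 518 of them called. With GC and length removed 1594 changed sign, 777 of them called. For lists, 238 values stayed on their side of the threshold, 45 lost the call, 10 gained it and 1 turned, the precursor list by fry (adjusted p 0.0211, down). The Zdhhc5 change and its alternatives were not analysed here. Every listed gene passed the filter, so leaving it out tested nothing. Genes at low counts had the widest errors, with an SE of 0.37 for Emcn at a control mean of 11.6 reads.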

Other observations

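The gene families in this paragraph and the next were chosen after their values were seen. Collagen genes rose for 18 of 25 listed members, with a median log2 fold change of 1.02 against 0.36 for GC-matched lists (adjusted p 0.003), and 0.77 with GC and length removed. The basement membrane collagens Col4a1 and Col4a2 rose in the mean of 2 libraries from 2458 to 6147 and from 1181 to 3248 normalised reads, and the interstitial collagen gene Col1a2 from 688.1 to 2215. Members that fell included Col20a1, from 5651 to 1098, Col11a1 and Col16a1. Col1a1, Col1a2 and Col3a1 are also members of the pericyte and fibroblast list, so the collagen rise is not separate from the rise of that list. Metallothionein and glutathione transferase genes, which handle metals and oxidants, rose for all 9 listed members, with a median of 0.69 that was not called beside GC-matched lists (adjusted p 0.34) and was 0.36 with GC and length removed. Mt3 rose from 15738 to 30156 and Gstm1 from 20172 to 32553. Voltage-gated and inward rectifier potassium channel genes rose for 8 of 13 listed members and fell for 5, with a median of 0.56 that was not called beside GC-matched lists (adjusted p 0.3) and was 0.26 with the GC trend removed. Among them Kcna1 fell from 1905 to 424.5 and Kcna2 from 4349 to 1550, and Kcnc1 rose from 1165 to 2013. Tubulin genes rose for 6 of 8, with a median of 0.58 (adjusted p 0.35 beside GC-matched lists), and 0.20 with GC and length removed. Among them Tubb4a, the form enriched in oligodendrocytes, fell from 54676 to 17398 while Tubb2a rose from 5454 to 8727 (log2 fold change 0.68, and 0.28 with GC and length removed).

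All 60 listed nuclear-encoded genes of the respiratory chain rose, with a median log2 fold change of 0.32 (adjusted p 0.37 beside GC-matched lists), which was 0.31 with the GC trend removed and 0.18 with GC and length removed, where 45 of 60 lay above 0. Of 10 listed genes of the mitochondrial genome 9 fell, all but the ribosomal RNA gene mt-Rnr1, with a median of -0.34. The mitochondrial median lay above that of GC-matched lists (-0.75, adjusted p 0.032), and it was 0.55 with the GC trend removed and 0.39 with GC and length removed, the opposite direction. Ribosomal protein genes rose for all 47 listed members, with a median of 0.24 (adjusted p 0.91 beside GC-matched lists), which was 0.11 with the GC trend removed and -0.01 with GC and length removed. Zinc finger genes named Zfp fell for 145 of 159 listed members, with a median of -0.80 against -0.53 for GC-matched lists (adjusted p 0.001), and -0.22 with the GC trend removed and -0.20 with GC and length removed. Proteasome genes rose for 12 of 15 listed members, with a median of 0.22, and kinesin genes fell for 16 of 18, with a median of -0.47, neither called beside GC-matched lists (adjusted p 0.91 and 0.45). With GC and length removed these medians were 0.14 and -0.19.

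Of the tests below, those of a library difference, of the sex ratio, of a lower share of lineage cells and of late against early genes were chosen only after the result was seen. The first pattern is that the oligodendrocyte lists fell, 53 of 56 listed members of the 3 lists being lower. The GC trend is argued against as the whole cause, because the median of these members was -1.50 before and -1.55 after its removal, and 54 of 56 then lay below 0. A lower share of lineage cells alone would raise markers of the other cell types alike. The astrocyte, neuron and microglia medians were close in the values as given, at 0.63, 0.67 and 0.70. They lay further apart with the GC trend removed, at 0.54, 0.91 and 0.53. With GC and length removed they were 0.48, 1.00 and 0.35. The endothelial median, of only 3 listed markers, was 1.86. Pericyte and fibroblast markers rose by 0.95 more on the log2 scale than astrocyte markers (permutation p 0.00074 across genes, which are not independent). Because precursors also express many astrocyte markers, and that pair was chosen after the values were seen, this difference cannot exclude a lower share. A change in composition that favours fibroblasts and pericytes also stays open. Panning with GalC and O4 antibodies is meant to leave such cells out. Yet Col3a1, the highest of their markers in the cKO libraries, stood at 5600 normalised reads there and at 1762 in the controls. Gfap, an astrocyte marker, had the highest count of any listed gene in all 4 libraries. Among listed members, mature genes fell further than newly formed ones by 0.87 in the median (2-sided permutation p 0.0093). Of the mature list 19 of 25 members were listed, and of the newly formed list 23 of 24. Members that were not called are thus missing mostly from the mature list, and with them the difference could be smaller. The difference was 0.37 with the GC trend removed (permutation p 0.04) and 0.57 with GC and length removed (permutation p 0.0084). Whether differentiation was delayed or blocked was not tested. Loss of Zdhhc5, Cre itself and the changed Olig1 locus cannot be told apart as causes, because the genotypes differ in all of them.

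The second pattern is that fold changes rose with GC content. Gene length alone is argued against, since rho was at least 0.28 within each of 5 bins of length. For the non-coding genes, GC content alone is argued against as well, because 179 of 207 fell, 86.5%. Of coding genes matched on GC content and level, 58.5% fell (52.7 to 63.8). Length was not matched. This comparison cannot tell whether GC content alone lies behind the trend among coding genes, because it does not test that trend. Non-coding genes had a median log2 fold change of -1.36 against -0.19 for coding genes. A library or RNA quality difference that coincides with genotype cannot be told apart from genotype with 2 libraries each, and the largest trend within a genotype, a rho of 0.17, was that between the cKO libraries.

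The third pattern is that Xist and 4 Y-linked genes all fell. Xist, transcribed in female cells from the inactive X chromosome, fell from 7743 ± 40.5 to 2336 ± 166 normalised reads (n = 2), and Ddx3y from 433.8 ± 11.6 to 137.1 ± 24.2. A different sex ratio of the pups is argued against as the whole cause, as it would move Xist and the Y-linked genes apart, whereas the log2 fold change was -1.73 for Xist and the median of the Y-linked genes -1.08. The trend with GC content and length stays open, because the 5 genes had a median of -1.12 and genes matched on both had medians from -1.14 to -0.38, though 2.9% of draws lay as low. With both trends removed Xist was at -0.86 and the Y-linked median at -0.10, so a different sex ratio together with these trends stays open.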
